A study of Homo sapiens with 2 samples.

How the data were processed

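RNA was taken at 48 h from MDA-MB-231 cells transfected with a THAP7-AS1 Smart Silencer or with si-NC, 1 library each, per the labels. Reads were processed with cutadapt, HISAT2 2.0.5 and StringTie on the hg19 build, per the submitters' processing notes, which give no role, order or setting for these tools. The authors' deposited table gives for each transcript an FPKM value (fragments per kilobase of transcript, scaled to the mapped total) in each library. Its header names no unit, and StringTie writes FPKM and TPM, so FPKM is a reading from the values, whose length-weighted sums were 71.4% and 69.9% of what all fragments would give. The annotation release, the strand setting and the filters are not given in the sources used here, so reads of overlapping antisense genes could not be told apart.

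The table held 39605 transcripts: a first block of 32574 that reached 0.5 FPKM in at least 1 library, then 7031 that did not. Transcript IDs carry the endings GENCODE gives to transcripts placed on the older build. They were matched without version to GENCODE release 29, which is on another build and was used only for symbols, transcript types, lengths, GC content and the chromosome; 99.5% matched, and the 179 others held 0.321% and 0.355% of the summed FPKM. Of the matched transcripts 99.7% were protein coding. Transcripts listed at 0 in both libraries numbered 2732.

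The control column was assigned by its name, si-NC. The column named si-v was assigned to the THAP7-AS1 silencer library by elimination, and it is called the si-v library throughout. As no transcript of THAP7-AS1 was listed, the target's level could not be used to check this assignment, and every direction given depends on it.

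The design had been written for gene values, and the choice to sum FPKM over the listed transcripts of a gene was made after the table was seen. This gave 12918 genes, of which 11046 reached 1 FPKM in at least 1 library. The log2 ratio was log2((si-v + 1)/(control + 1)), where the pseudocount of 1 understates differences of low genes. Genes were counted as higher or lower at 2-fold on this scale. No p-value or model of the difference between the groups was used, since 1 library per group gives no spread between cultures. The intervals given cover counting error within these libraries, or, for an odds ratio, the number of genes in it. The fold threshold, the gene lists and the rule for named genes were chosen before the data were examined. The rule named the listed genes of the target locus, the 12 highest and 12 lowest ratios among genes of at least 5 FPKM, the 2 highest and 2 lowest members of each list, and ACTB and GAPDH; other list members given as examples were chosen after their values were seen. A few genes that the rule named are not reported here.

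For each of 35 gene lists the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression, for lists with at least 5 members past the filter. A list was said to stand apart at a percentile of 2.5 or below or 97.5 or above, as a description of these libraries. The lists MYC targets and immediate-early genes share MYC, and ATF3 is in the immediate-early and the unfolded protein response lists.

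In genes with a single listed transcript, low values times length peaked at 91.1 in the control and at 84.1 in the si-v library. This peak was taken as the worth of 1 fragment. Of the 89 and 80 values near it, 51.7% and 46.2% lay within 5% of it. Fragment numbers are therefore approximate, and whole counts were not recovered. They came to 7830000 and 8320000 on the listed transcripts, which implies about 11000000 and 11900000 in all if the unit is FPKM. Intervals for single genes are exact Clopper-Pearson intervals at 95% on these fragments, widened by the Bonferroni rule where they are counted over many genes, and cover counting error only. They leave out the division of reads among transcripts and the variation between cultures.

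The steps were tested on simulated data with the expression of 10842 genes and no real difference except in a seeded set. The noise was set by hand to an SD of log2 0.30, below the 0.49 seen over the genes of these libraries, so the rates describe the steps and not false calls in these data. The 2-fold rule picked up 96.0% of genes changed 3-fold up and 86.0% of those changed 3-fold down, 8.00% of those changed 1.5-fold up, and 0.0400% of unchanged genes, and 3.50% of unshifted lists lay outside the limits.

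For fragments per gene the fragments were scaled to the summed FPKM, so that the pseudocount of 1 stands for 26.2 fragments in the control and 27.8 in the si-v library and shrinks the ratio of genes with few fragments. Alternatives were other pseudocounts, filters, scalings and thresholds, and, added after the data were seen, fragments per gene, the most abundant transcript only, the removal of the trend with GC content and length, and random lists matched on GC content in addition. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.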

Results

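The data were 1 RNA-seq library from MDA-MB-231 cells, an established human triple-negative breast cancer line, transfected with a Smart Silencer against THAP7-AS1 (a commercial mix of siRNAs and antisense oligonucleotides), and 1 library from the same line transfected with the negative control si-NC, both taken at 48 h. THAP7-AS1 is a long noncoding RNA gene beside THAP7 on chromosome 22. The question was which messenger RNAs differ in level after its silencing. The deposited table gave expression values, read here as FPKM, for 39605 transcripts in a control column and a column headed si-v. The si-v column was taken as the silenced library by elimination, since the other column is named si-NC and the series has 2 libraries; the meaning of v is not stated. With 1 library per group the differences have no replicate check, and every statement below describes these 2 libraries. A peak among the low values put the depth at about 7830000 fragments on the listed transcripts in the control library and 8320000 in the si-v library.

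The targeted gene could not be followed, because 0 of the 3 transcripts of THAP7-AS1 in the reference annotation were among the listed transcripts, which were nearly all protein coding; the silencing itself was therefore not checked here. Its neighbour THAP7, a zinc finger protein gene, stood at 1.5 FPKM in the control and 1.60 in the si-v library. These values rest on about 19 and 22 fragments, which leave a log2 ratio anywhere from -0.86 to 1.06 possible (95% counting interval). The other listed genes of the locus were close in level as well: LZTR1 at 1.86 and 2.39 FPKM, KLHL22 at 3.60 and 3.77, and PI4KA at 6.47 and 6.27. SNAP29 stood at 22.6 and 19.8, MED15 at 13.7 and 11.1, and the adaptor gene CRKL at 17.4 and 13.1. With the GC content and length trend removed the log2 ratio turned from 0.06 to -0.23 for THAP7 and from 0.05 to -0.13 for KLHL22. None of these 7 genes reached a 1.5-fold difference. As a list they had a median log2 ratio of -0.04, at percentile 43.79 of random lists of the same size and expression.

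Across the transcriptome the libraries were close, with 8977 of 11046 genes (81.3%) within 1.5-fold of each other. At 2-fold or more, 262 genes were higher and 275 lower in the si-v library. Among the genes with the largest differences upward were DAG1, which encodes the laminin receptor dystroglycan, at 1.69 FPKM in the control and 20.4 in the si-v library (log2 2.99), ANKRD11, a chromatin regulator, at 5.29 and 46.3 (2.91), and VPS35, a retromer subunit, at 2.56 and 20.8 (2.61). Downward, NKTR, a cyclophilin-related protein, went from 22.6 in the control to 1.25 in the si-v library (-3.39), and ARPC2, a subunit of the Arp2/3 actin-nucleating complex, from 131 to 16.9 (-2.88). The genes at 4-fold or more numbered 20 higher and 17 lower.

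The rest of the 12 largest differences upward held SDAD1, from 3.70 FPKM in the control to 34.9 in the si-v library (log2 2.93), PRXL2B, from 0.389 to 9.19 (2.87), and ARHGAP21, from 4.79 to 35.7 (2.66). RRAD went from 0.657 to 9.05 (2.60), TRIM16L from 0.135 to 5.55 (2.53), and CYBC1 from 1.14 to 10.3 (2.40). They also held 3 readthrough genes, whose annotated transcripts run across adjacent genes: NEDD8-MDP1 from 1.08 to 16.9 (3.11), C7orf55-LUC7L2 from 3.99 to 28.3 (2.55), and CHURC1-FNTB, listed at 0 in the control and at 6.44 in the si-v library. The 12 largest differences downward also held UHMK1, from 28 to 4.44 (-2.41), TGFB1I1, a focal adhesion protein, from 32.9 to 5.95 (-2.28), the mitochondrial ribosomal protein gene MRPL10, from 18.2 to 3.02 (-2.26), and EMP1, from 5.74 to 0.437 (-2.23). Others were EVPL, which encodes the desmosomal protein envoplakin, from 17.1 to 2.88 (-2.22), the Wnt receptor gene FZD6, from 12 to 1.79 (-2.21), and TWF1, from 23.8 to 4.37 (-2.20). The readthrough gene FAM47E-STBD1 went from 5.21 to 0.437 (-2.11), and SHTN1 from 8.45 to 1.23 (-2.08).

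With counting intervals widened to hold at 95% over all 11046 genes together, no change was excluded for 234 of the 262 higher and 249 of the 275 lower genes. The intervals do not cover how reads were divided among transcripts. Of the 24 genes with these largest differences, 18 had fewer coding transcripts listed than annotated. Others had unlisted transcripts of other types, such as TRIM16L with 1 of 16 annotated transcripts listed and SDAD1 with 2 of 10. The unlisted coding transcripts may not set the 18 apart, since the table listed 39327 coding transcripts against 83064 annotated. The share over all genes was not computed. In ANKRD11, with 2 of 19 coding transcripts listed, a single transcript went from 0.00993 to 41.1 FPKM. Read from the most abundant transcript, the log2 ratio was 5.38 for ANKRD11, 4.44 for SDAD1, 3.90 for ARHGAP21, 3.64 for DAG1 and -3.19 for UHMK1, each larger than for the gene. On fragments per gene the log2 ratio was 3.87 for DAG1, 3.54 for ARHGAP21 and -2.86 for EMP1. It was 2.06 for NEDD8-MDP1, 1.73 for CYBC1 and 1.58 for RRAD, where the pseudocount shrinks the ratio of genes with few fragments. The gene counts were 486 higher and 473 lower with a pseudocount of 0.1, and 683 and 706 when each gene was read from its most abundant transcript only.

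Of 33 gene lists with enough measured members, 11 lay outside the central range of random lists matched on expression. The number expected was 1.65 if the genes of a list varied independently. Genes of 1 list can move together between any 2 cultures, so with 1 library per group the excess is no measure of an effect of the silencer. Genes encoded in mitochondrial DNA, genes of G2/M and mitosis, MAPK feedback genes and hypoxia response genes were lower in the si-v library. NF-kB cytokines and chemokines, MYC targets, immediate-early genes, extracellular matrix and integrin genes, interferon-stimulated genes, ribosomal protein genes, and unfolded protein response and ATF4 target genes were higher. The mitochondrially encoded genes had a median of log2 -0.78. For the other lists the differences were small, with medians from -0.44 to 0.51.

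**Figure D1:**
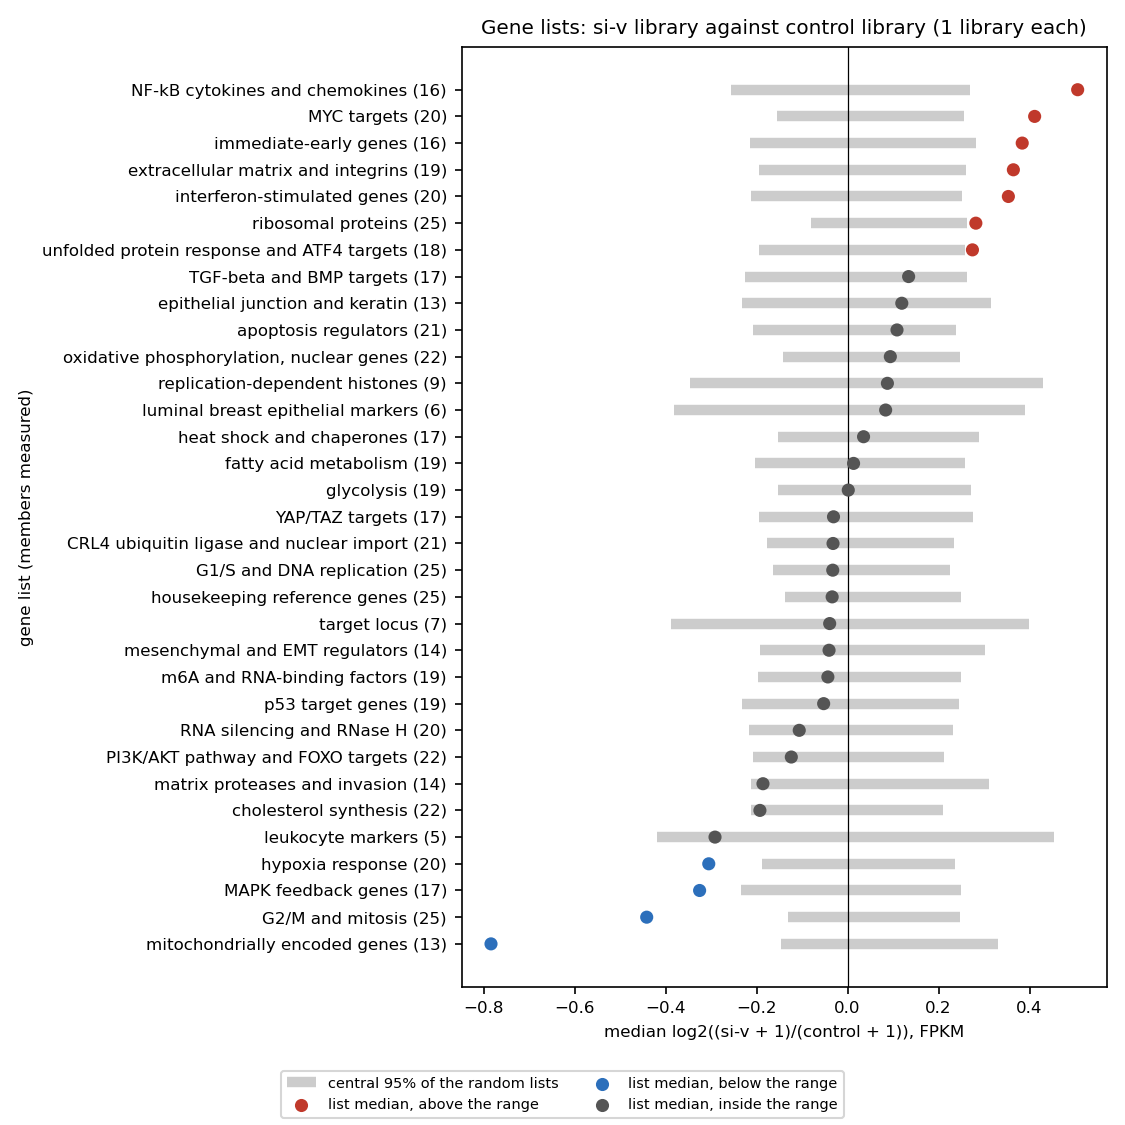
Median log2 ratio of each gene list (dots; members measured in parentheses) between the si-v and the control library, with the central 95% range of 10000 random lists of the same size and expression (grey bars). The mitochondrially encoded genes lie lowest at -0.78, and the NF-kB cytokines and chemokines highest at 0.51.

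All 13 listed genes of the mitochondrial genome, which encode subunits of the respiratory chain and ATP synthase, were lower in the si-v library, 11 of them by 1.5-fold or more. MT-ND4L stood at 4093 FPKM in the control and 1728 in the si-v library (log2 -1.24), MT-ND5 at 1326 and 680.0 (-0.96), and the smallest difference was that of MT-ND6, at 301 and 228 (-0.40), close to MT-ND3 at 676 and 506 (-0.42). The list median of -0.78 lay below all 10000 random medians, whose lists were drawn gene by gene. As the 13 genes lie on 1 genome and may move together, they are not 13 separate observations. Together these genes took 12% of the summed FPKM in the control and 6.93% in the si-v library. Summed FPKM weighs short transcripts more, and as a share of the fragments over all genes they took about 4.47% and 2.60%. The nuclear genes of oxidative phosphorylation had a median of 0.09 (percentile 66.42); NDUFB9 stood at 18.1 and 36.8 FPKM, SDHB at 30.9 and 46.2, NDUFS3 at 17.6 and 10.9, and COX5A at 56.0 and 38.3.

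Mitotic genes were lower in the si-v library for 22 of 25 members, 7 of them by 1.5-fold or more. DLGAP5, a spindle assembly factor, stood at 119 FPKM in the control and 57.5 in the si-v library (log2 -1.04), and the kinetochore motor gene CENPE at 40.4 and 23.0 (-0.79). The differences were smaller for their most abundant transcripts (-0.39 and -0.23), and for DLGAP5 on fragments per gene (-0.52). The cyclin gene CCNB1 stood at 145 and 98.8 (-0.55) and the mitotic kinase gene PLK1 at 39.9 and 25.2 (-0.65). The proliferation marker MKI67 was placed against this direction, at 34.6 and 63.5 (0.86), as was the survivin gene BIRC5, at 20.3 and 27.7 (0.43). The list median of -0.44 was below all 10000 random medians, and the members had a median GC content of 43.2%. Genes of G1/S and DNA replication had a median of -0.03 (percentile 24.05), from MCM2 at 18.6 and 31.3 FPKM and RFC4 at 29.5 and 41.2 (0.47, but -0.24 for its most abundant transcript) to CCNE1 at 12 and 7.68 and CCNE2 at 17.5 and 12.2. Replication-dependent histone genes had a median of 0.09 over 9 members (percentile 64.81), with HIST1H2BD at 1.93 and 6.41, HIST1H1C at 25.7 and 51.4, HIST1H4C at 3.0 and 1.48, and HIST1H2BK at 25.6 and 22.3.

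Hypoxia response genes were lower for 14 of 20 members, with a median log2 ratio of -0.31 (percentile 0.10). The glycolytic regulator gene PFKFB4 stood at 14.8 FPKM in the control and 7.88 in the si-v library (-0.83, and -0.51 on fragments per gene) and the mitophagy receptor gene BNIP3L at 24.3 and 15.8 (-0.59). VEGFA, at 14.6 and 29.2 (0.96), and ANGPTL4, at 1.28 and 3.08 (0.84), lay the other way, though the ratio of VEGFA was 0.41 on fragments per gene and -0.05 for its most abundant transcript. MAPK feedback genes had a median of -0.33 (percentile 0.30) with 12 of 17 members lower and none at 1.5-fold. PHLDA1 stood at 125 and 89.9 FPKM (-0.47) and ETV5 at 28.3 and 20.1 (-0.47), while the phosphatase gene DUSP5 stood at 7.83 and 10.9 (0.43) and ETV4 at 15.5 and 18.8 (0.26). For the MAPK list the percentile was 19.3 with the most abundant transcript of each gene only and 6.44 after the GC content and length trend was removed (median -0.17), so it was then no longer set apart.

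NF-kB cytokines and chemokines had the highest list median, log2 0.51 (percentile 99.98), with 8 of 16 members 1.5-fold or more higher and none that much lower. IL6 stood at 0.380 FPKM in the control and 2.09 in the si-v library (1.16), the NF-kB feedback inhibitor gene TNFAIP3 at 4.62 and 11.1 (1.11), and the neutrophil chemokine gene CXCL8 at 2.25 and 5.13 (0.92). CSF2, a myeloid growth factor gene, was listed at 0 in the control and at 1.63 in the si-v library, while BIRC3 stood at 7.17 and 5.66 (-0.30, but 0.03 with the GC content and length trend removed) and CXCL1 at 2.07 and 1.79 (-0.14). Many of these genes were low, and with members of at least 5 FPKM only the median was 0.36 at percentile 96.70, inside the limits.

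Immediate-early genes had a median of log2 0.38 (percentile 99.68), with 12 of 16 members higher. ATF3, a stress-induced transcription factor also held by the unfolded protein response list, stood at 1.43 FPKM in the control and 6.26 in the si-v library (1.58, and 0.89 for its most abundant transcript), and IER2 at 9.64 and 21.0 (1.05). FOSL1, the AP-1 subunit with the highest level of the list, lay the other way at 739 and 463 (-0.67), and ZFP36 stood at 14.3 and 12 (-0.23). The members had a median GC content of 56.8%, and after the GC content and length trend was removed the median was 0.23 at percentile 97.36, just inside the limit. Interferon-stimulated genes had a median of 0.35 (percentile 99.66), with 15 of 20 members higher and 6 of them by 1.5-fold or more. IFI6 stood at 5.59 and 10.7 FPKM (0.83), IFI27 at 0.607 and 1.91 (0.86), and the antiviral effector genes BST2 at 86.3 and 138 (0.67) and ISG15 at 24.3 and 39.0 (0.66). The IFI27 values rest on about 5 and 14 fragments, with a 95% counting interval of -0.19 to 3.20 that includes no change. IRF9, a subunit of the interferon-activated transcription factor, was at 2.29 and 0.698 (-0.96), and IFIT5 at 11 and 7.88 (-0.43). With members of at least 5 FPKM only the interferon list was at percentile 95.26.

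In the unfolded protein response and ATF4 target list, 11 of 18 members were higher, with a median of log2 0.27 (percentile 98.25). DDIT3, the gene of the stress factor CHOP, stood at 1.99 FPKM in the control and 13.7 in the si-v library (2.30), and the asparagine synthetase gene ASNS at 6.89 and 17.6 (1.24). The endoplasmic reticulum chaperone gene HSPA5 was at 165 and 227 (0.46). HERPUD1 at 8.31 and 3.32 (-1.11, -0.47 on fragments per gene and -2.50 for its most abundant transcript) and DNAJB9 at 6.47 and 4.46 (-0.45), both of endoplasmic reticulum protein degradation, lay the other way. The list kept all 18 members and its median with a filter of 5 FPKM, but was inside the limits of the random lists drawn after it (percentile 96.87), as it was with the most abundant transcript only (median 0.10, percentile 71.77). Heat shock and chaperone genes had a median of 0.04 (percentile 38.80), from CCT5 at 140 and 197 FPKM and HSPA1B at 54.9 and 75 to HSPE1 at 87.6 and 63.8 and HSPA4L at 9.93 and 7.73.

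MYC targets, mostly genes of ribosome assembly and nucleolar function, had a median of log2 0.41 (percentile 99.95), with 15 of 20 members higher. NOLC1, a nucleolar phosphoprotein, stood at 44.7 FPKM in the control and 109.7 in the si-v library (1.28), and ODC1, the first enzyme of polyamine synthesis, at 42.0 and 81.9 (0.95). MYC itself was level at 7.79 and 7.75 FPKM, PPAN stood at 17.5 and 8.84 (-0.91, and -1.97 for its most abundant transcript) while the readthrough gene PPAN-P2RY11 stood at 2.96 and 18.0, and GNL3 at 32.2 and 22.3 (-0.51). Ribosomal protein genes were higher for 23 of 25 members by small amounts, with a median of 0.28 (percentile 98.66). RPS14 stood at 52.7 and 87.2 FPKM (0.72) and RPS24 at 322 and 455 (0.50, but -0.46 for its most abundant transcript), with RPL15 at 138 and 124 (-0.16) and RPL5 at 1022 and 978 (-0.06). Read from the most abundant transcript only, the ribosomal list had a median of 0.14 at percentile 79.8. Transcripts of ribosomal proteins share sequence with many pseudogenes, which the counting could have split.

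Extracellular matrix and integrin genes were higher for 15 of 19 members, with a median of log2 0.36 (percentile 99.72) and a median GC content of 55.4%. The basement membrane collagen gene COL4A1 stood at 9.79 FPKM in the control and 17.6 in the si-v library (0.78), the integrin gene ITGB3 at 1.88 and 3.57 (0.67, and 0.39 for its most abundant transcript), and the matricellular protein gene THBS1 at 162 and 227 (0.49). The collagen-binding integrin gene ITGA2 had the largest difference of the list and the opposite sign, at 10.5 and 3.24 (-1.44), and ITGAV stood at 17.8 and 14.2 (-0.31, but 1.38 for its most abundant transcript).

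**Figure D2:**
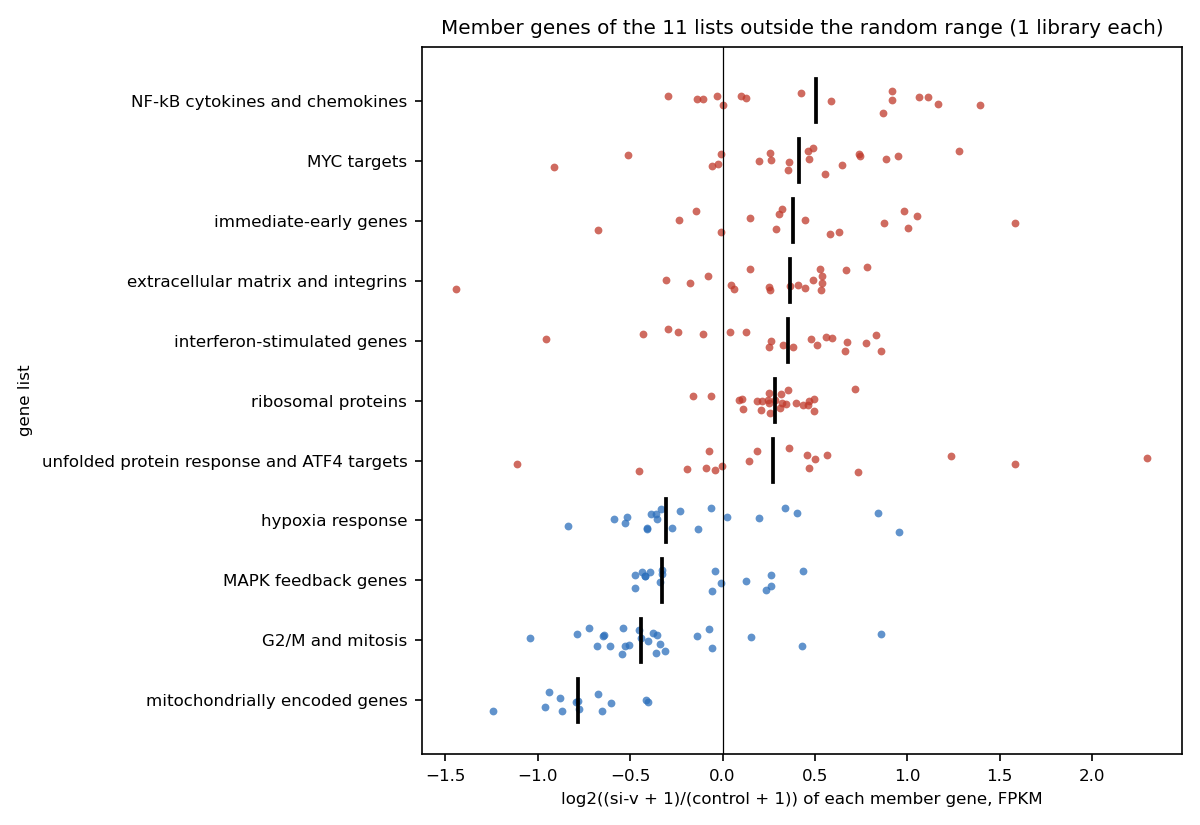
Log2 ratio of each member gene (dots) and list median (black bars) for the 11 lists outside the random range, red where the list was higher and blue where it was lower in the si-v library. All 13 mitochondrially encoded genes lie below 0, while other lists hold members on both sides, such as ITGA2 at -1.44 among the matrix and integrin genes.

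Lists of epithelial and mesenchymal state and invasion did not stand apart. The mesenchymal and EMT regulator list had a median of log2 -0.04 (percentile 21.85), with LOX at 36.7 FPKM in the control and 23.2 in the si-v library, CD44 at 152 and 114, ITGA5 at 25.3 and 28.5, and SNAI1 at 0.376 and 1.07. Epithelial junction and keratin genes had a median of 0.12 (percentile 72.88), with KRT7 at 131 and 184, EPCAM at 11.3 and 12.8, CLDN3 at 3.28 and 2.24, and ESRP2 at 1.17 and 0.998. Matrix proteases and invasion genes had a median of -0.19 (percentile 4.32, and 2.11 with GC content matched as well, outside the limits), and its members parted: the collagenase gene MMP1 stood at 27.8 and 50.1 and TIMP2 at 37.5 and 60.5, against PLAU at 48.5 and 36.6 and CTSL at 38.0 and 30.7. TGF-beta and BMP targets had a median of 0.13 (percentile 84.44), from INHBA at 1.39 and 3.48 and ID3 at 12.2 and 20.6 to TGFBR2 at 29 and 17.7 (-0.68, and -2.58 for its most abundant transcript) and SMAD6 at 2.05 and 1.12. YAP/TAZ targets had a median of -0.03 (percentile 25.84). AJUBA stood at 12.5 and 24.3 (0.91, 0.64 on fragments per gene and 2.79 for its most abundant transcript) and YAP1 at 47.2 and 75.6. TEAD1, at 47.6 and 29.4, and F3, at 508 and 379, lay the other way.

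Lists of survival signalling and ubiquitin ligase genes lay inside the random range as well. The p53 target genes had a median of log2 -0.05 (percentile 34.31). BAX stood at 13.6 FPKM in the control and 27.2 in the si-v library, and FDXR at 0.131 and 1.71 (1.26, and 0.59 for its most abundant transcript). RRM2B was at 13.3 and 7.61 (-0.73, but -0.29 on fragments per gene and -0.16 for its most abundant transcript). MDM2 was at 8.15 and 5.17 (-0.57, but 0.13 on fragments per gene and 0.24 for its most abundant transcript). With members of at least 5 FPKM only, the p53 list had a median of 0.40 at percentile 98.29, outside the limits. Apoptosis regulators had a median of 0.11 (percentile 81.25), with DIABLO at 45.3 and 73.4 and CASP2 at 2.23 and 1.03. For PI3K/AKT pathway genes and FOXO targets the median was -0.12 (percentile 14.44), with AKT1 at 28.5 and 38.1 (0.41, but -0.11 for its most abundant transcript). PIK3R1 stood at 2.11 and 3.46 (0.52, but -0.12 on fragments per gene and -0.76 for its most abundant transcript), INPP4B at 19.1 and 11.3, and IRS1 at 12.8 and 8.60. Genes of the CRL4 ubiquitin ligase and nuclear import had a median of -0.03 (percentile 29.49) and no member at 1.5-fold, with COPS8 at 6.81 and 9.0, NEDD8 at 78.3 and 97.7, the importin genes TNPO1 at 47.6 and 32.2 and KPNA2 at 111 and 86.1.

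Metabolic and RNA-related lists were likewise within the range. Glycolysis genes had a median of log2 0.00 (percentile 25.89), from ENO1 at 474 FPKM in the control and 708 in the si-v library and PFKM at 12.6 and 19.9 to PFKL at 21.5 and 10.5 and GAPDH at 313 and 219. Cholesterol synthesis genes had a median of -0.19 (percentile 3.94, and 2.14 with the GC content and length trend removed, outside the limits) with 16 of 22 members lower, among them MSMO1 at 14.7 and 7.19 and HMGCS1 at 6.91 and 4.06, against NSDHL at 8.41 and 10.1 (0.24, and 1.0 for its most abundant transcript) and MVK at 2.79 and 3.39. Fatty acid metabolism genes had a median of 0.01 (percentile 50.13), with SREBF1 at 6.40 and 11.4, FADS1 at 60.2 and 30.5, and ELOVL5 at 106 and 73.4. ACACA stood at 9.36 and 13.7 (0.51, but 0.09 on fragments per gene, and 3.37 for its most abundant transcript). The m6A and RNA-binding factors had a median of -0.04 (percentile 28.40), with YTHDF3 at 1.8 and 5.30, FTO at 3.52 and 5.86, YTHDC2 at 8.13 and 6.23, and IGF2BP3 at 8.53 and 6.62. RNA silencing and RNase H genes, only some of which act with silencing oligonucleotides, had a median of -0.11 (percentile 16.50). DICER1 stood at 23.8 and 11.7, PRKRA at 11.3 and 6.38, DGCR8 at 1.08 and 3.36, and RNASEH2A at 56.9 and 88.2. The list of nuclear long noncoding RNAs and snoRNA hosts had 0 listed members and was not analysed here.

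Housekeeping reference genes had a median of log2 -0.03 over 25 members (percentile 16.62), and of -0.16 on fragments per gene (0.795), outside the limits. ACTB stood at 96.1 FPKM in the control and 93.9 in the si-v library and GAPDH at 313 and 219 (-0.51), while TBP, at 26.8 and 11.6, and PPIA, at 412 and 193, differed by more than 2-fold. The log2 ratio of PPIA was -1.09, but -0.62 on fragments per gene and -4.60 for its most abundant transcript. CHMP2A at 52.3 and 83.5 and PSMB4 at 51.9 and 73.9 lay the other way. Among markers of other cells, the luminal breast epithelial list had a median of 0.08 over 6 measured members (percentile 66.56), with the receptor gene ERBB2 at 4.65 and 17.4 (1.71), XBP1 at 16.7 and 28.4 (0.73), ERBB3 at 1.61 and 1.03 (-0.37), and GATA3 at 2.65 and 2.18 (-0.20). For their most abundant transcripts the log2 ratio was 0.11 for XBP1, 0.10 for ERBB3 and 0.56 for GATA3. Leukocyte markers had a median of -0.29 over 5 members (percentile 8.04), with the lysosomal membrane protein gene LAPTM5 at 23.9 and 5.90 (-1.85), LCP1 at 11.3 and 8.78, CD68 at 47.8 and 55.0, and LYZ at 2.39 and 2.98. Of fibroblast and endothelial markers 3 passed the filter, too few for a percentile: COL1A1 at 0.482 and 1.14, PDGFRB at 1.01 and 0.641, and ACTA2 at 2.11 and 0.825.

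The log2 ratio also moved with base composition and transcript length. Over 7945 genes of at least 5 FPKM, ranked by GC content into 5 groups of equal size, the median log2 ratio was -0.22 in the group of lowest GC content and 0.26 in that of highest, with a Spearman correlation across genes, which are not independent replicates, of 0.386. By length, the medians went from 0.13 in the shortest to -0.14 in the longest group. Low-GC lists such as the mitotic genes (43.2%) and the mitochondrially encoded genes (44.3%) were lower in the si-v library and high-GC lists such as the immediate-early genes (56.8%) higher, while interferon-stimulated genes (47.7%) and ribosomal protein genes (47.6%) were higher and hypoxia response genes (53.6%) lower. Among random lists matched on GC content as well as expression, all 11 lists stayed outside the limits on the same side.

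**Figure D3:**
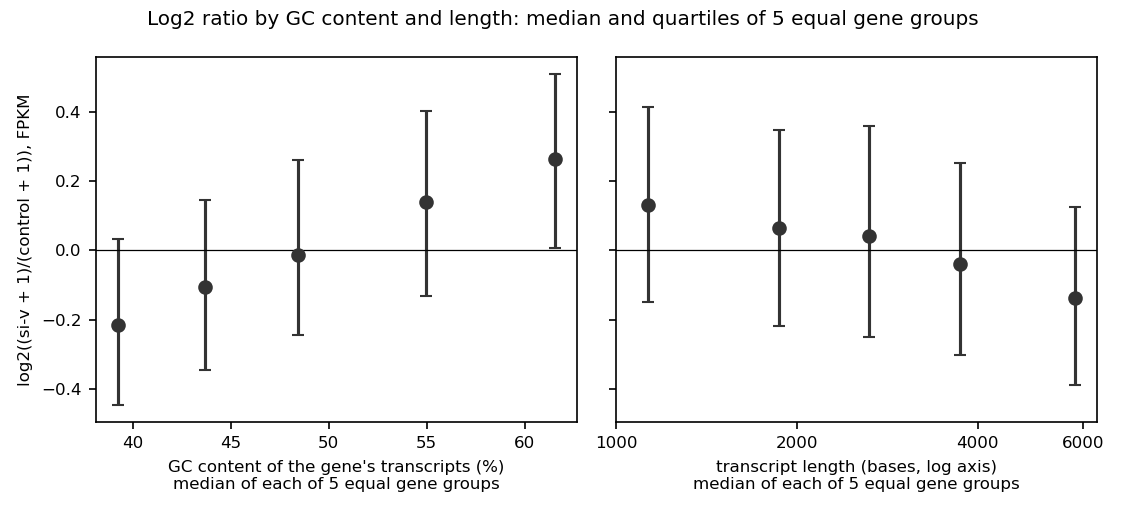
Median log2 ratio of si-v over control (dots) with the lower and upper quartiles over genes (bars) in 5 equal groups of the 7945 genes by GC content and by transcript length. The medians go from -0.22 to 0.26 with GC content and from 0.13 to -0.14 with length.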

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

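Fragments per gene, the most abundant transcript only, the GC content and length trend, and GC-matched random lists were added after the data were seen. The counts of 262 higher and 275 lower genes were 486 and 473 with a pseudocount of 0.1, 683 and 706 with the most abundant transcript only, and, by construction, 1085 and 984 at 1.5-fold and 20 and 17 at 4-fold; for the pseudocount and the most abundant transcript the cause was not tested. They stayed within 1.5 times under the other scalings, filters and corrections, and the share of higher genes between 44.6% and 54.1%. Of the 537 genes, 531 were shared when ratios were centred, 381 with fragments per gene and 429 with the trend removed. The lists that stood apart kept their sign under every setting. With a filter of 5 FPKM 3 moved inside the limits: interferon-stimulated genes (median 0.32, percentile 95.26) and NF-kB cytokines and chemokines (0.36, 96.70), which lost members, and the unfolded protein response list (0.27, 96.87), which lost none, so that only the random lists differed. With the most abundant transcript only it was the unfolded protein response list (0.10, 71.77), ribosomal proteins (0.14, 79.8) and MAPK feedback genes (-0.15, 19.3), and with the trend removed immediate-early genes (0.23, 97.36) and MAPK feedback genes (-0.17, 6.44); the cause was not tested. Lists newly outside the limits were p53 targets with the filter of 5 FPKM, where the median turned from -0.05 to 0.40 (98.29), matrix proteases with a pseudocount of 0.1 (-0.24, 2.16) or GC-matched lists (-0.19, 2.11), cholesterol synthesis with the trend removed (-0.20, 2.14), and housekeeping genes with fragments per gene (-0.16, 0.795). Of 162 named genes, 2 changed sign with fragments per gene, MDM2 (0.13) and PIK3R1 (-0.12). In this setting 37 moved by more than the distance from the middle to the end of their counting interval. In 10 the fold differed by over 1.5 times. In 6 of these 10, genes with few fragments in 1 library, the value left the interval of the fragments themselves, an effect of the pseudocount. Without a pseudocount 467 of the 537 genes were at 2-fold in fragments on the same side, and 2 lay on the other side. With the most abundant transcript only 11 changed sign, among them AKT1 (-0.11), ERBB3 (0.10), GATA3 (0.56), ITGAV (1.38), MDM2 (0.24), PIK3R1 (-0.76), RFC4 (-0.24), RPS24 (-0.46) and VEGFA (-0.05). Here 58 moved by more than the same distance within their interval, and in 24 the fold differed by over 1.5 times. With the trend removed 34 moved by more than that distance and 3 changed sign, BIRC3 (0.03), KLHL22 (-0.13) and THAP7 (-0.23). With a pseudocount of 0.1 none did, and in 16 the fold differed by over 1.5 times. None of the named genes at 2-fold changed sign. Scaling moved the median of all genes by 0.02 at most. Other settings for THAP7-AS1 were not run, since the gene was not listed. No paired analysis was possible because each group has 1 library. Depth limits low genes, such as THAP7 with 19 and 22 fragments.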

Other observations

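Symbol families and dominant transcripts were looked at after the data were seen, as were the tests on readthrough genes and counting error. Among 72 groups of at least 15 measured genes with a shared symbol root, 9 lay outside the limits with random lists matched on expression. With GC content matched too 8 did, and 6 did under both. For each of the 2 matchings 3.6 were expected if the genes of a group varied independently, which related genes may not do. Ubiquitin-conjugating and ligase genes with UBE symbols were lower in the si-v library for 29 of 38 members (median log2 -0.26, percentiles 0.03 and 0.17), such as UBE2T at 56.9 FPKM in the control and 30.3 in the si-v library and UBE2D1 at 15 and 8.98, while UBE2G2 stood at 6.83 and 25.6 and UBE3A, an E3 ligase gene, at 11.7 and 23.9. The ZNF zinc finger genes were higher by a little, 226 of 394 members (0.09, 99.97, and above all 10000 with GC content matched), in spite of a low median GC content of 44.8%. NUDT hydrolase genes were higher for 14 of 20 (0.25, 98.46 and 98.75), among them NUDT1, which removes oxidised nucleotides, at 24.0 and 41.2. CCDC genes were higher for 44 of 74 (0.14, 99.11 and 99.20) and ZC genes for 12 of 17 (0.32, 99.14 and 99.73). Outside this count, as a group merged from 2 roots, 61 of 75 ribosomal protein genes with RPL or RPS symbols were higher (0.24, 99.84 and 99.96), the fixed 25 among them. The RPL root alone, 40 of 48 higher, was among the 6, while the RPS root, 29 of 39 higher, was inside the limits (97.07 and 95.73). The root groups also hold similarly named genes, such as the kinase gene RPS6KB1.

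Single transcripts, with fewer reads behind each, passed 2-fold more often than gene totals, with 2925 higher and 2606 lower of 25024 (11.7% and 10.4%) against 2.37% and 2.49% of genes. In 1271 of 5779 genes (22%) with several listed transcripts and at least 5 FPKM in both libraries, another transcript was the most abundant in the si-v library, and in 499 of them both transcripts differed by at least 2-fold in opposite directions. The gene total stayed nearly level in 217 of the 499. Among these the chromatin gene SMARCD2 had 27.6 and 27.7 FPKM in all. Its transcript leading in the control went from 23.7 to 0.0278 and that leading in the si-v library from 0.491 to 24.4. SIN3A went from 23.7 to listed at 0 in its control transcript, with the other listed at 0 and 21.0. The thioredoxin reductase gene TXNRD1 showed the same exchange, at 257 and 0 against 8.76 and 165. Such exchanges were not checked against reads.

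The 11 gene lists that stood apart might follow the trend of the log2 ratio with GC content. Among random lists matched on GC content and expression they stayed outside the limits: percentile 0 for G2/M and mitosis and 0 for mitochondrially encoded genes, 0.05 for hypoxia response, 0.42 for MAPK feedback, 98.51 for extracellular matrix and integrins, 99.92 for interferon-stimulated genes, 100 for NF-kB cytokines and chemokines, 98.44 for the unfolded protein response, 99.38 for ribosomal proteins, 98.2 for immediate-early genes and 99.9 for MYC targets. This argues against GC content as the whole cause. Removing the trend with GC content and length together took immediate-early genes from a median of 0.38 to 0.23 (percentile 97.36) and MAPK feedback genes from -0.33 to -0.17 (6.44), and ended their calls as the medians came nearer to 0; GC content and length were not removed apart, so a part played by length stays open. Variation between cultures, the silencer and a difference in library preparation stay open, and no biological explanation could be tested with 1 library per group.

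The genes at 2-fold or more included 16 readthrough genes that have a listed component gene; whether that is more than expected was not tested. A candidate explanation is that reads of the locus went to the readthrough gene in 1 library and to a component gene in the other. In 9 of the 16 loci a component differed by at least 1.5-fold in the opposite direction, as in TMEM189-UBE2V1, at 12.9 and 65.9 FPKM, with UBE2V1 at 109 and 46.3. Over all genes, 9.82% were higher and 8.91% lower by that much, a rate per gene. A locus with more than 1 listed component had more than 1 way to meet the rule. The rate for loci would therefore be higher, and it was not computed. In CHURC1-FNTB the gene FNTB met the rule, at 8.04 and 3.54, but CHURC1 stood at 13.9 and 18.2, the other way. In NEDD8-MDP1 and C7orf55-LUC7L2 no component met it. These readthrough genes stood at 1.08 and 16.9 FPKM and at 3.99 and 28.3. With their components the loci held 84.4 and 118 FPKM, and 108 and 153. A transfer of that size need not move a high component such as NEDD8, at 78.3 and 97.7, by 1.5-fold, so the rule cannot decide for these loci.

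The 537 genes at 2-fold or more could in part reflect the division of reads among annotated transcripts. This was tested on the genes of at least 5 FPKM only, so the lower ones among the 537 were left out. Genes with a single transcript in the reference annotation, where it allows no division within the gene, passed 2-fold in 13 of 326 cases (3.99%). Genes with more did in 369 of 7619 (4.84%). The expression-matched odds ratio was 0.815 (95% interval 0.459 to 1.45), so the 13 genes are too few to decide. Reads of such genes can still be divided with another gene, as C7orf55-LUC7L2, with 1 annotated transcript, has the component gene LUC7L2. The annotation used for the counting is not given either, so this group may not be free of such division. Counting error is argued against as the whole cause: with intervals widened to hold at 95% over all 11046 genes together, which allows for picking genes by size, no change was excluded for 483 of the 537. Variation between cultures remains open and untested, and so does the knockdown.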
